A study of Homo sapiens with 6 samples.

How the data were processed

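Total RNA was extracted with a phenol-based reagent, quantified by spectrophotometry and used at 250 ng per array to make biotin-labelled complementary RNA, which was hybridized to Affymetrix arrays, per the labels' protocols. The 6 samples fall into 2 groups of 3 arrays by their titles. The deposited table holds log2 values for 49395 probe sets on each array. They were made by the authors with RMA (robust multi-array averaging, which comprises background correction, quantile normalization and a summary of the probes of a set) and Affymetrix Expression Console, per the submitters' processing notes. Versions, settings and filters are not given in the sources used here. RMA makes the overall distribution of signals alike between arrays, so a change shared by most genes is removed from the deposited values. No value was missing, and every column was mapped to a sample by its name.

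Probe sets were named from the platform annotation. Of the probe sets, 44988 had 1 gene symbol, 1832 had several, 2473 had none and 102 were controls. Those with 1 symbol gave 18132 genes, of which 18112 had their symbol in the RefSeq gene table of assembly GRCh38.p14, and no symbol was changed. Each gene was represented by its probe set with the highest mean over the 6 arrays. Probe sets of a gene can disagree in direction, and the number that shared the sign of the brightest one was counted. Some genes of the lists are not analysed here. The background level of an array was the 95th percentile of the signals of 340 olfactory receptor genes, 5.99 on average, and 12 of these genes exceeded it on all arrays.

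The MM231-FGD5-cas9 group was compared with the MM231 group in limma 3.58.1 under R 4.3.3 (lmFit and eBayes without trend or robust settings), on the deposited log2 values with no further normalization. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. SDs are between the 3 arrays of a group and SEs are those of limma. Gene lists were tested with camera at its preset correlation of 0.01 and adjusted over 34 lists, each with at least 5 measured genes. Single values were compared by exact two-sided permutation over the arrays. The genes named were FGD5 and EGFR, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and the significant members with the largest changes in each list, up to 4 for a called list and up to 2 for any other. Members named outside this rule were chosen after their values were seen. Groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists of myeloid genes, lymphoid genes and genes expressed in MDA-MB-231 cells were written afterwards. Numbers and figures outside limma were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

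The procedure was tested on simulated data built on the means and spread of these arrays. Over 18132 simulated genes it recovered 22% of log2 changes of 0.3, 66% of those of 0.5, 96% of those of 1 and 100% of those of 2. It called 1 of 17903 unchanged genes. A simulated list shifted by 0.3 was called and 0 other lists were. The simulation did not include correlation between genes. It left 17903 of 18132 genes unchanged, whereas 8150 genes changed in the data. The adjustment was therefore stricter in the simulation, and the recovery rates may be too low for the data.

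Alternatives were a replicate block, leaving out each array, filters on dim genes, repeated quantile normalization, centring each array on its median, other choices of probe set, other variance models, array weights, a test against a 1.2-fold change, an estimated correlation between genes, fry and lists of bright members. Scaling to the poly-A spike-ins and a filter at the background level were added after the data were seen.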

Results

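Gene expression was measured in total RNA on 6 Affymetrix human arrays. The labels name the cells as MDA-MB-231, a breast cancer line of basal, mesenchymal-like character, and place 3 arrays in a group called MM231 and 3 in a group called MM231-FGD5-cas9. Cas9 is an RNA-guided nuclease used to edit genes. FGD5 encodes an exchange factor for the small GTPase CDC42. The labels do not state which form of Cas9 was used or whether FGD5 was to be lost or induced. The comparison asks how the transcriptome of the samples labelled MM231-FGD5-cas9 differed from that of the samples labelled MM231. Values were log2 signals after robust multi-array averaging, and 18132 genes were measured. Array medians lay between 6.39 and 6.44. The correlation across probe sets, which are not independent replicates, was 0.996 to 0.999 in the 6 pairs of arrays within a group and 0.977 to 0.980 in the 9 pairs between groups. The number of arrays limits the precision of each value. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

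FGD5, the gene named with Cas9, was below the background level in both groups, and no change in it was detectable. The brightest of its 4 probe sets read 4.86, 4.72 and 4.54 on the 3 arrays labelled MM231 and 4.80, 4.87 and 5.01 on the 3 labelled MM231-FGD5-cas9. The means were 4.71 ± 0.16 and 4.89 ± 0.10 (log2, SD, n = 3 each), against a background level of 5.99 taken from olfactory receptor genes. The difference of 0.19 ± 0.09 (SE) had an adjusted p of 0.133 in limma with Benjamini-Hochberg adjustment and an exact two-sided permutation p of 0.2. With 3 arrays against 3, the smallest p the exact test can give is 0.1. Without MM231 replicate 1 the difference was 0.26 with an adjusted p of 0.0373, and after scaling to the poly-A spike-ins it was 0.71 with an adjusted p of 2.77e-09. That scaling shifts every gene alike and moved the median difference of all genes from 0.07 to 0.58. Its p-value therefore does not single out FGD5. The background level was 6.02, 5.89 and 5.76 on the arrays labelled MM231 and 6.11, 6.11 and 6.06 on those labelled MM231-FGD5-cas9. A small rise in a signal below that level, as without MM231 replicate 1, therefore cannot be read as a change in FGD5. Transcript levels at probe sets whose place relative to the edit is not given do not check the edit itself. EGFR, the receptor for epidermal growth factor, was also below the background level in both groups, at 5.23 ± 0.26 and 5.32 ± 0.11 (log2, SD, n = 3 each), with an adjusted p of 0.543 in limma with Benjamini-Hochberg adjustment. All 8 EGFR probe sets had higher means in the MM231-FGD5-cas9 group. In a limma fit over all probe sets 2 of them passed, by 0.29 and 0.24 (adjusted p = 0.0236 and 0.0493). Each of the 8 lay below the background level on every array, and that level was itself higher in this group. These rises therefore do not show a change in EGFR. After scaling to the spike-ins EGFR was 0.62 higher (adjusted p = 1.95e-07), near the median of 0.58 over all genes, so this p-value does not single out EGFR.

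On 2 lists written after the values had been seen, most myeloid genes were bright on all 6 arrays and most of the genes chosen as expressed in MDA-MB-231 cells were near the background level. Of 35 measured myeloid genes, 33 exceeded the background level on all 6 arrays, with medians of 10.42 in the MM231 group and 10.8 in the MM231-FGD5-cas9 group. Of 32 measured genes expressed in MDA-MB-231 cells, 6 did so, with medians of 5.42 and 5.47. Mesenchymal-like genes outside that list, which leukocytes also express, were bright, with VIM at 13.48 and 13.03, MSN at 13.07 and 13.10, S100A4 at 12.58 and 12.05 and CD44 at 11.59 and 11.35. MPO, the peroxidase of neutrophil granules, read 13.74 ± 0.07 and 13.93 ± 0.04 (log2, SD, n = 3 each). Serglycin (SRGN) read 13.41 ± 0.11 and 14.14 ± 0.01. The caveolin genes CAV1 and CAV2, the receptor tyrosine kinase AXL and the surface nucleotidase NT5E lay below 5.99 in both groups. Of 15 leukocyte markers on a list fixed before the data were examined, 10 exceeded the background level on all arrays, among them CORO1A and PTPRC, which encodes CD45. The same count was 5 of 18 for luminal breast markers, 1 of 10 for basal breast markers, 6 of 23 for epithelial genes, 7 of 22 for mesenchymal genes, 6 of 18 for endothelial markers and 5 of 19 for lymphoid genes. For comparison, 57.1% of all genes did so. No cell type was assigned, and the groups are named by their array labels.

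**Figure D1:**
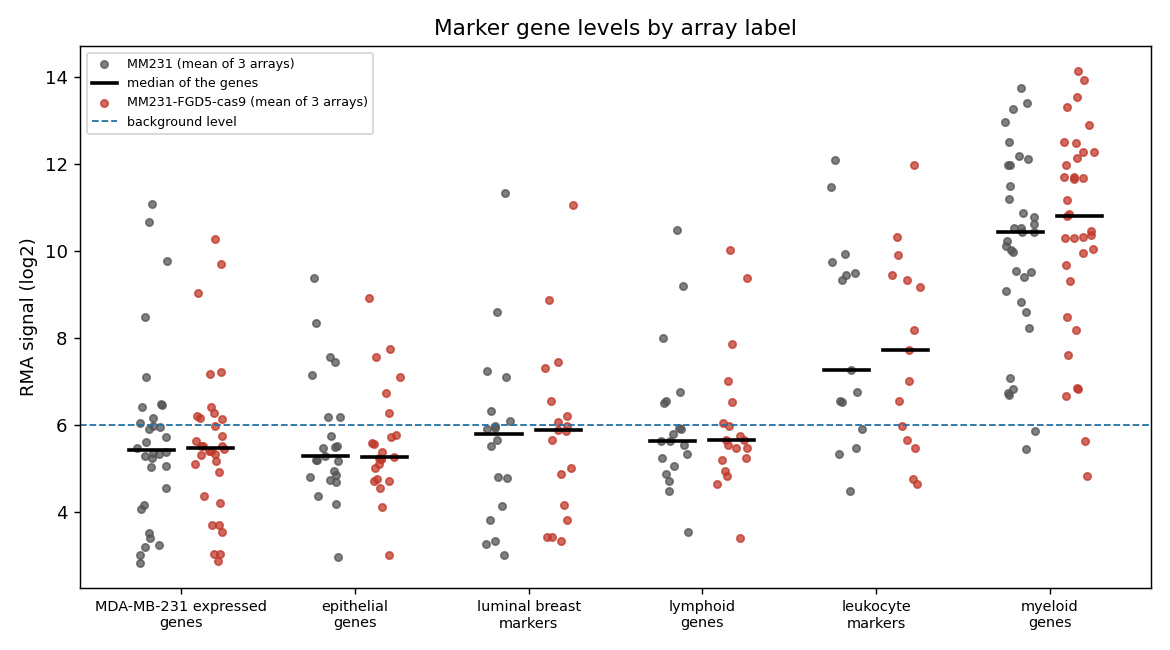
Mean RMA signal (log2, vertical axis) of each measured gene in 6 marker lists (horizontal axis), with grey points for the 3 arrays labelled MM231 and red points for the 3 labelled MM231-FGD5-cas9, black bars for the median of each list and a dashed line for the background level of 5.99. The medians of the myeloid genes were 10.42 and 10.8 and those of the MDA-MB-231 expressed genes were 5.42 and 5.47.

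In the arrays labelled MM231-FGD5-cas9, 23 of 25 genes on a list of the stress factor ATF4 and its targets were lower than in the arrays labelled MM231. On the same comparison, 25 of 29 mitosis genes and 25 of 29 S phase genes were higher. PRTN3, which encodes the granule enzyme proteinase 3, rose by 5.05 ± 0.07 on the log2 scale (SE, 33.1-fold, adjusted p = 9.58e-10). TRIB3, a pseudokinase induced by amino acid stress, fell by 4.26 ± 0.07 (SE, 19.1-fold, adjusted p = 3.03e-09). INHBE, an inhibin beta subunit gene, went from 9.36 ± 0.09 to 4.33 ± 0.14 (SD, n = 3 each), below the background level, and was at least 9.59-fold lower (adjusted p = 3.35e-09). In limma with Benjamini-Hochberg adjustment, 8150 of 18132 genes changed (44.9%), with 4069 higher and 4081 lower. Of these, 1214 changed at least 2-fold, 399 higher and 815 lower, and 7009 of the changed genes exceeded the background level in at least 1 group mean. The arrays of the groups did not overlap for 54.9% of genes, where chance gives 10%. After scaling to the poly-A spike-ins, which moved the median log2 fold change of all genes from 0.07 to 0.58, the split was 14504 higher and 1394 lower. Directions are given relative to the deposited scaling.

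The other large rises took in defensins, surface proteins and an eosinophil granule gene, and 5 of them lay in genes below the background level on all arrays labelled MM231. For a gene below the background level on all arrays of a group, the fold is a lower bound, computed from the background level of those arrays where it exceeded the gene's own signal. DEFA4, a neutrophil defensin, was at least 5.41-fold higher, the membrane protein gene TMEM200A at least 3.71-fold, the epithelial defensin gene DEFB1 at least 2.84-fold, VIT at least 2.68-fold and the transcription factor gene TFEC at least 1.41-fold. ROPN1L, which exceeded the background level on 1 of the 3 arrays labelled MM231, went from 5.83 ± 0.20 to 8.60 ± 0.05 (SD, n = 3 each). The nucleotide receptor gene P2RY2 rose by 2.43 ± 0.15 (log2, SE), the NAD-consuming ectoenzyme gene CD38 by 2.42 ± 0.10, the eosinophil ribonuclease gene RNASE2 by 2.39 ± 0.07 and the mitochondrial dicarboxylate carrier gene SLC25A10 by 2.31 ± 0.08. RRP7A rose by 2.45 ± 0.07, on a probe set that may also bind transcripts of a near-identical pseudogene. Adjusted p-values of these rises in limma with Benjamini-Hochberg adjustment lay between 1.33e-08 and 2.93e-06.

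Large falls took in a death receptor gene, signalling regulators and developmental genes. TNFRSF25 fell by 4.23 ± 0.09 (log2, SE, 18.7-fold). The histone demethylase gene KDM7A fell by 3.41 ± 0.08, the stress-responsive transcription factor gene ATF5 by 3.38 ± 0.10, the AP-1 subunit gene JUN by 3.31 ± 0.08 and the homeobox gene HOXB9 by 3.23 ± 0.09. The pseudokinase gene TRIB2 was at least 8.72-fold lower, IGDCC4 at least 7.38-fold and the sulfotransferase gene CHST2 at least 4.08-fold. Adjusted p-values of these falls in limma with Benjamini-Hochberg adjustment lay between 1.06e-08 and 1.96e-07. All 12 largest rises and 12 largest falls kept their direction under every scaling tried. Their size fixed this in advance, since the smallest, 2.31 for SLC25A10, far exceeded the shift of 0.52 of scaling to the spike-ins.

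Of 34 gene lists fixed before the data were examined, 11 were called by camera with its preset correlation, and 0 with a correlation estimated per list, where 2 lists had an unadjusted p under 0.05. By fry, which asks whether a list moves on balance one way and does not compare it with other genes, 23 were called. Probe sets of a gene did not always share a direction. The sign of the brightest was shared by 4 of 5 probe sets for SKI and TM7SF2, 3 of 5 for HES1, 3 of 4 for FGD5, 2 of 3 for DLL1, HLA-B, RPL3, SREBF2 and TIMP1, and 1 of 2 for TIMP2.

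Targets of ATF4, the transcription factor of amino acid deprivation and the integrated stress response, fell together. Of 25 measured genes on the list, which counts ATF4 itself, 23 fell, 0 rose and 2 did not pass the test. When adjusted over the list alone, 24 passed. The median log2 fold change was -1.15 (camera adjusted p = 7.31e-14; adjusted p = 0.0744 with an estimated correlation). Besides TRIB3, the asparagine synthetase gene ASNS fell by 2.98 ± 0.08 (log2, SE, 7.89-fold), the lipoprotein receptor gene VLDLR by 3.17 ± 0.09 (9.01-fold) and the mTORC1 inhibitor gene DDIT4 by 2.52 ± 0.11 (5.73-fold), with adjusted p-values of 4.28e-08, 4.51e-08 and 3.77e-07. The genes of serine synthesis PHGDH and PSAT1 fell by 2.07 and 1.33 on the log2 scale and ATF4 itself by 0.60, which was a difference of -0.09 that did not pass after scaling to the spike-ins. The amino acid carrier genes SLC7A5 and SLC1A5 fell by 0.44 and 0.27 but were above 0 after scaling to the spike-ins. CHAC1 and ALDH1L2 had differences of 0.14 and 0.29 that did not pass the test. After scaling to the spike-ins the list median was -0.63. The poly-A spike-ins were 0.52 lower in the same arrays and the 18S ribosomal RNA probe sets 1.95 lower.

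Genes of cell division rose. Of 29 measured mitosis genes, 25 rose, 0 fell and 4 did not pass, with 26 when adjusted over the list alone and a median of 0.80 (camera adjusted p = 5.64e-08; adjusted p = 0.654 with an estimated correlation). The mitotic kinesin gene KIF20A rose by 2.12 ± 0.18 (log2, SE), the cyclin gene CCNB1 by 1.98 ± 0.20, and the genes of the spindle regulators PLK1 and TPX2 by 1.32 ± 0.10 and 1.32 ± 0.11. Of 29 measured S phase genes, 25 rose, 0 fell and 4 did not pass, with 25 when adjusted over the list alone and a median of 0.57 (camera adjusted p = 6.27e-07; adjusted p = 0.654 with an estimated correlation). The replication fork gene CDC45 rose by 1.40 ± 0.07, the helicase gene MCM2 by 1.07 ± 0.11 and the cyclin gene CCNE1 by 0.99 ± 0.08. MM231 replicate 1 stood apart within its group, at 7.06 for KIF20A and 8.94 for CCNB1 against 7.80 and 9.80 in MM231 replicate 2. In the MM231-FGD5-cas9 arrays the 18S ribosomal RNA probe sets were 1.95 lower, the poly-A spike-ins 0.52 lower and the ACTB 5' minus 3' difference 0.61 higher.

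Genes of mitochondrial respiration and of sterol synthesis were also higher. Of 32 measured genes of oxidative phosphorylation, 22 rose, 0 fell and 10 did not pass, with 24 when adjusted over the list alone and a median of 0.26 (camera adjusted p = 3.92e-05; adjusted p = 0.654 with an estimated correlation). NDUFA9, NDUFA8, COX6B1 and ATP5F1D, subunit genes of complex I, cytochrome c oxidase and ATP synthase, rose by 1.00 ± 0.06, 0.82 ± 0.09, 0.84 ± 0.08 and 0.70 ± 0.07 (log2, SE). Of 19 measured genes of cholesterol synthesis, 14 rose, 3 fell and 2 did not pass, with 17 when adjusted over the list alone and a median of 0.41 (camera adjusted p = 0.0098; adjusted p = 0.654 with an estimated correlation). The call was lost, at an adjusted p of 0.0701, when the probe set of largest variance stood for each gene. DHCR7, a late enzyme of the pathway, rose by 1.58 ± 0.09, FDPS by 1.03 ± 0.07, NSDHL by 0.92 ± 0.07 and HMGCS1 by 0.91 ± 0.12. PMVK and TM7SF2 fell by 0.56 and 0.53 on the deposited scale and differed by -0.04 and -0.02 after scaling to the spike-ins, and SREBF2, a transcription factor gene of the pathway, fell by 0.33 but was above 0 after scaling to the spike-ins. In the same arrays the poly-A spike-ins were 0.52 lower.

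Target genes of the ERK pathway moved mainly down on the deposited scale. Of 20 measured ERK pathway targets, 13 fell, 2 rose and 5 did not pass, with 15 when adjusted over the list alone and a median of -0.57 (camera adjusted p = 0.000579; adjusted p = 0.654 with an estimated correlation), which was -0.05 after scaling to the spike-ins. PHLDA1 fell by 1.79 ± 0.09 (log2, SE), the ERK phosphatase gene DUSP6 by 1.31 ± 0.12 and the transcription factor gene ETV4 by 1.19 ± 0.07, and the phosphatase gene DUSP5 was at least 2.27-fold lower. FOSL1 rose by 0.78. EPHA2 rose by 0.32, from 5.94 to 6.26, and did not exceed the background level on all arrays. MYC and FOS had differences of 0.01 and 0.10 that did not pass, and for FOS 1 of 4 probe sets had that sign.

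Proteases of tissue invasion and NF-kB targets moved mainly down on the deposited scale, though both list medians were above 0 after scaling to the spike-ins, at 0.30 and 0.19. Of 27 measured proteases and inhibitors, 13 fell, 1 rose and 13 did not pass, with 14 when adjusted over the list alone and a median of -0.22 (camera adjusted p = 0.00292; adjusted p = 0.654 with an estimated correlation). The collagenase gene MMP1 was at least 5.47-fold lower and the stromelysin gene MMP10 at least 3.21-fold. The gelatinase gene MMP9 fell by 1.63 ± 0.08 and the cathepsin gene CTSK by 1.02 ± 0.16 (log2, SE). The protease inhibitor genes TIMP1 and TIMP2 fell by 0.95 and 0.76, and the cathepsin gene CTSL rose by 0.53. Of 24 measured inflammatory cytokines and NF-kB targets, 14 fell, 2 rose and 8 did not pass, with 16 when adjusted over the list alone and a median of -0.32 (camera adjusted p = 0.00347; adjusted p = 0.654 with an estimated correlation). The adhesion molecule gene ICAM1 fell by 2.21 ± 0.11 and the interleukin gene IL1B by 1.01 ± 0.15, and the chemokine gene CXCL3 was at least 1.43-fold lower. CXCL8 and IL6 had differences of 0.05 and 0.07 that did not pass, with that sign on 1 of 3 and 1 of 2 probe sets.

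Among TGF-beta targets, the inhibitory SMAD genes showed the largest falls, while the list median of -0.16 on the deposited scale was 0.36 after scaling to the spike-ins. Of 22 measured, 10 fell, 2 rose and 10 did not pass, with 13 when adjusted over the list alone (camera adjusted p = 0.0098; adjusted p = 0.502 with an estimated correlation). The call was lost, at an adjusted p of 0.0972, when the probe set of largest variance stood for each gene. SMAD7 was at least 3.93-fold lower and SMAD6 at least 3.57-fold. The receptor gene BMPR2 fell by 1.11 ± 0.09 and the co-repressor gene SKI by 1.08 ± 0.08 (log2, SE), and COL4A1 rose by 0.80.

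Ribosomal protein and antigen presentation lists were called at higher p-values, and their medians of -0.08 and -0.12 were 0.44 and 0.40 after scaling to the spike-ins, which ended both calls. Of 33 measured ribosomal protein genes, 8 fell, 0 rose and 25 did not pass, with 7 when adjusted over the list alone (camera adjusted p = 0.03; adjusted p = 0.654 with an estimated correlation). RPL13, RPL3, RPL10A and RPL5 fell by 0.41, 0.40, 0.29 and 0.25 on the deposited scale and were higher by 0.11, 0.11, 0.23 and 0.26 after scaling to the spike-ins. Of 3 probe sets for 28S ribosomal RNA, the 5' and middle ones were 1.17 and 0.51 lower and the 3' one 0.38 higher in the same arrays. Of 21 measured antigen presentation genes, 9 fell, 2 rose and 10 did not pass, with 11 when adjusted over the list alone (camera adjusted p = 0.0375; adjusted p = 0.654 with an estimated correlation). The peptide-trimming enzyme gene ERAP1 fell by 1.25 ± 0.06 (log2, SE), the class I genes HLA-B and HLA-C by 1.13 ± 0.09 and 0.93 ± 0.06 and the transporter gene TAP1 by 0.86 ± 0.06. The probe sets for HLA-B and HLA-C may also bind transcripts of related class I genes. TAP2 and PSMB10 rose by 0.60 and 0.61. Ribosomal proteins lost their call without MM231 replicate 3, MM231-FGD5-cas9 replicate 2 or MM231-FGD5-cas9 replicate 3 (adjusted p = 0.0668, 0.0609 and 0.0616), and antigen presentation without MM231 replicate 1 (adjusted p = 0.0631). Over all 19 alternatives, ribosomal proteins were called in 8 and antigen presentation in 12. Repeated quantile normalization ended both calls (adjusted p = 0.235 and 0.0533), and centring the arrays ended that of ribosomal proteins (adjusted p = 0.0711).

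**Figure D2:**
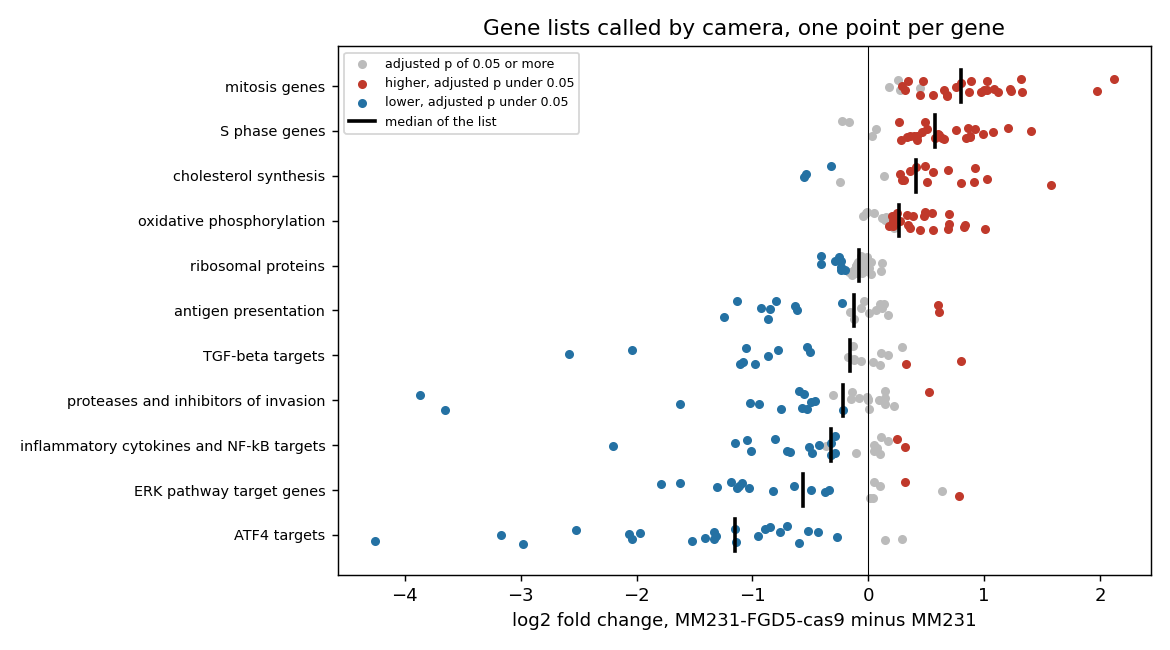
Log2 fold change of MM231-FGD5-cas9 over MM231 arrays (horizontal axis, 3 arrays each) for every measured gene of the 11 lists called by camera (vertical axis), with red points for genes that were higher, blue for lower and grey for those that did not pass the test, and black bars for the list medians. Medians ran from -1.15 for ATF4 targets to 0.80 for mitosis genes on the deposited scale, and those of ribosomal proteins, antigen presentation, TGF-beta targets, proteases and NF-kB targets were above 0 after scaling to the spike-ins.

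Some of the 23 lists that were not called held large changes in both directions. In the unfolded protein response list, 10 of 20 measured genes rose and 6 fell. SDF2L1, an endoplasmic reticulum chaperone cofactor gene, rose by 1.95 ± 0.06 (log2, SE), whereas HERPUD1, of the degradation machinery, fell by 1.77 ± 0.07. The angiogenic factor gene VEGFA fell by 3.13 ± 0.07 (8.73-fold) and the mitophagy receptor gene BNIP3L by 1.73 ± 0.11, in a glycolysis and hypoxia list where 9 of 27 rose and 8 fell. The interferon-induced genes IFIT1 and IFI6 rose by 2.25 ± 0.11 and 1.25 ± 0.10, with 11 of 28 higher and 5 lower. In the p53 target list, 10 of 22 fell and 2 rose, and SESN2 and BBC3 fell by 2.04 ± 0.07 and 2.00 ± 0.09. The p53 list had a camera adjusted p of 0.113 and was called under 4 of 19 alternatives. Its median of -0.04 was 0.48 after scaling to the spike-ins. SESN2 is on the ATF4 list as well. In the Wnt and Notch list, 12 of 32 fell and 3 rose. The Notch ligand gene DLL1 fell by 2.32 ± 0.12 and the Notch target gene HES1 by 1.65 ± 0.07, and the camera adjusted p was 0.0697. That list was called under 9 of 19 alternatives, with adjusted p-values from 0.000137 to 0.654 over all of them. Among these were the fits without MM231 replicate 3 or MM231-FGD5-cas9 replicate 2 (adjusted p = 0.0332 and 0.0474), the filter at the median level (0.0169) and scaling to the spike-ins (0.0092). In 11 of the lists not called, the median and the direction of camera differed in sign, as for the Wnt and Notch list with a median of 0.05 and a mean of -0.33.

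Lists tied to FGD5 and EGFR signalling were not called by camera on all members. Of 24 measured FGD family members and CDC42 partners, 7 fell, 3 rose and 14 did not pass, with 10 when adjusted over the list alone (camera adjusted p = 0.434). FGD3 fell by 0.91 ± 0.07 and CDC42EP3 by 0.84 ± 0.09 (log2, SE). Of 21 EGFR family members, ligands and turnover genes, 6 fell, 3 rose and 12 did not pass, with 10 when adjusted over the list alone (camera adjusted p = 0.488). The EGFR list was called with its bright members alone (median -0.42, adjusted p = 0.029), and fry called both lists (adjusted p = 0.00236 for EGFR and 0.00621 for FGD). The ligand gene TGFA, which exceeded the background level on 2 of the 3 arrays labelled MM231-FGD5-cas9, fell by 2.30 ± 0.12 and the feedback inhibitor gene ERRFI1 by 1.80 ± 0.10. Among leukocyte markers, 5 of 15 fell and 2 rose (camera adjusted p = 0.336), with the integrin gene ITGAM lower by 1.31 ± 0.09 and PTPRC by 1.15 ± 0.08. SPARC, a matricellular protein gene of the mesenchymal list, rose by 1.07 ± 0.08, and the transcription factor gene ZEB1 fell by 0.96 ± 0.10. EPCAM fell by 0.46 ± 0.07 but had a difference of 0.06 after scaling to the spike-ins. KRT8, above the background level on 1 of the 3 arrays labelled MM231, was 0.29 ± 0.09 higher on its brightest probe set, while 1 of its 8 probe sets had that sign.

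Control probe sets differed between the groups as well. The poly-A spike-ins, added to RNA before labelling, read 7.75 ± 0.06 in the MM231 group and 7.23 ± 0.10 in the MM231-FGD5-cas9 group (log2, SD, n = 3 each). The hybridization spike-ins read 11.15 ± 0.09 and 10.99 ± 0.02. The 18S ribosomal RNA probe sets read 11.02 ± 0.69 and 9.07 ± 0.11. The 5' probe set for ACTB, compared with the 3' probe set, was -0.92 ± 0.06 in the MM231 group and -0.32 ± 0.08 in the MM231-FGD5-cas9 group. For each of these the groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 can give.

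**Figure D3:**
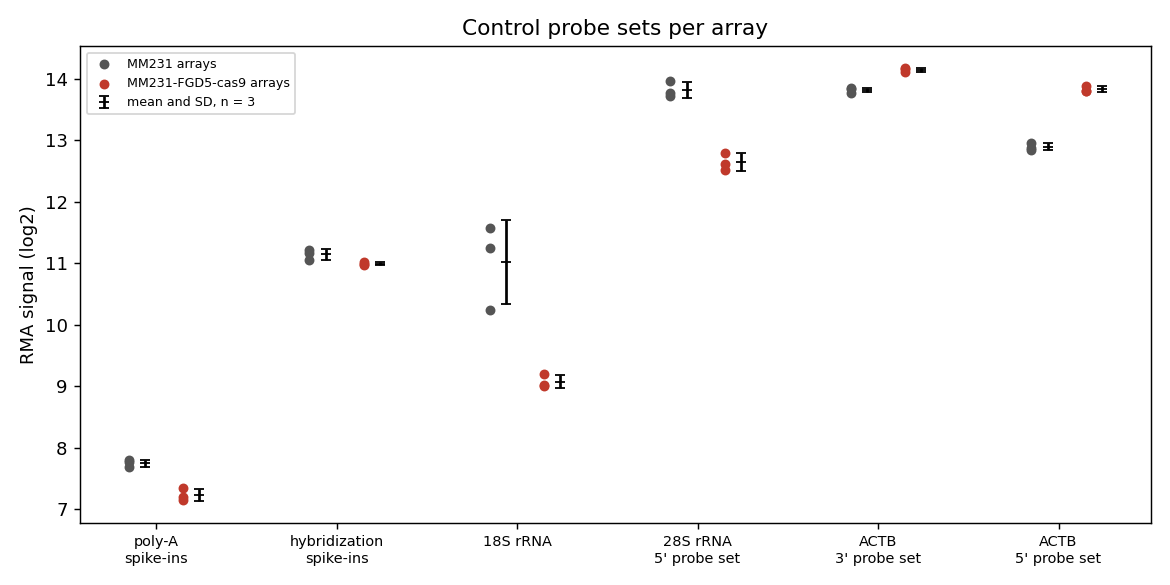
RMA signal (log2, vertical axis) of control probe sets (horizontal axis) on each of the 6 arrays, with grey points for MM231, red points for MM231-FGD5-cas9 and black bars for the mean and SD of 3 arrays. The 18S ribosomal RNA signal averaged 11.02 in the MM231 group and 9.07 in the MM231-FGD5-cas9 group.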

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

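The test of a shared shift in RNA content was chosen after the result was seen, while those on splits of the arrays and on neighbouring genes were set beforehand.

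Signals outside the gene comparison also differed between the groups. The 5' control probe set for ACTB was higher by 0.94 on the log2 scale in the MM231-FGD5-cas9 group, and the difference of its 5' and 3' signals rose by 0.61 while that of GAPDH rose by 0.05, each with an exact two-sided permutation p of 0.1, the smallest possible. Of 4305 probe sets without a single gene symbol, 898 were higher and 793 lower in limma with Benjamini-Hochberg adjustment. Together these were a smaller share than the 44.9% of genes that changed. Each gene was represented by its brightest probe set, so the shares are unlike measures, and no separate difference was read from them.

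Nearly as many genes rose as fell on the deposited scale, and their number was large for groups of 3 arrays. Some technical explanations for the 8150 changed genes were therefore weighed. A single difference in messenger RNA content or spike-in amount would move all genes alike, but 399 genes were at least 2-fold higher and 815 at least 2-fold lower, which argues against it as the whole cause. Copy number differences between the cells cannot be told apart from other causes, because directly neighbouring genes correlated at 0.07 (one-sided permutation p = 0.001, the smallest that 1000 permutations can give) and genes 10 places apart at 0.01 (p = 0.149), while the largest mean over windows of 51 genes, -0.38 from CEP152 to HERC1 in the gene order of assembly GRCh38.p14, had a permutation p of 0.012. Only 10 splits of the 6 arrays exist, too few for a share under 0.05. The real one of the 10 gave 8150 changed genes and 1214 changed at least 2-fold, against 0 and 0 at most in the others. Every other split mixes both labels within its groups. Differences between the labels then widen the spread within groups, so its 0 calls add no information. For gene lists the real split called 11 and the highest other split 8. The edit of FGD5 remains open, since transcript levels do not check it. So do differences between clones, cultures or cell types of the groups, which were not tested as causes of these changes. In the MM231-FGD5-cas9 arrays 18S ribosomal RNA was 1.95 lower and the ACTB 5' minus 3' difference 0.61 higher. What lies behind these control differences was not tested as a cause either.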

How the results depend on the processing

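Scaling to the poly-A spike-ins and the filter at the background level were chosen after the data were seen, and all other settings were set beforehand. Leaving out each array gave 6790 to 9563 changed genes, 3193 to 5433 higher, 3597 to 4130 lower, 1172 to 1259 changed at least 2-fold, 10 to 11 lists and an FGD5 difference of 0.11 to 0.26, which passed only without MM231 replicate 1. Testing every probe set gave 20638 changed, 10475 higher, 10163 lower and 2955 at least 2-fold, because more features were tested. Scaling to the spike-ins gave 15898 changed, 14504 higher, 1394 lower and 1980 at least 2-fold, since its shift of 0.52 applies to every gene; 5463 of these genes were called with the same sign on the deposited scale. Under it FGD5 was 0.71 higher, EGFR 0.62, EPCAM 0.061, RPL13 0.11, RPL3 0.11, RPL10A 0.23 and RPL5 0.26. Other probe sets turned KRT8 to -0.10 (mean of probe sets) and -0.42 (largest variance) and RPL3 to 0.51 (largest variance); the cause was not tested. Called lists numbered 7 with the probe set of largest variance, 0 with an estimated correlation and 23 by fry, which asks another question. The test against a 1.2-fold change passed 4098 genes. Over all settings, 1798 results on named genes kept their side of the threshold, 13 lost the call, 1 gained it and 8 reversed. For lists, judged by the direction of the set test against other genes, these numbers were 575, 29, 29 and 0. Direction was checked only for results called in the main fit. EGFR, not called there, ran from -0.016 to 0.239 when single arrays were left out. The medians of 5 called lists changed sign under scaling to the spike-ins. Ribosomal proteins lost their call under 11 of 19 alternatives and antigen presentation under 7, and the Wnt and Notch list was called under 9. Labels share replicate numbers. Same-numbered arrays deviated from their group means with correlations of 0.06, 0.01 and 0.07, and different-numbered arrays with correlations from -0.10 to 0.04. These values are small, but they cannot exclude that same-numbered samples were handled together. With the replicate block 8029 genes changed, 4008 higher and 4021 lower, 7741 of them shared with the same sign, 1214 at least 2-fold, with 11 lists and FGD5 at 0.19 (adjusted p = 0.169). Variance models with trend and robust settings were run for genes and not for lists. Signals below the background level of 5.99 limit what can be said of dim genes, FGD5 among them.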

Other observations

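The tests of probe naming, of admixture, of myeloid identity, of FGD5 loss and of ATF4 probe sets, and the lists of myeloid, lymphoid and MDA-MB-231 expressed genes, were chosen after the results were seen.

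Myeloid genes, on a list written after the values were seen and not tested as a set, went both ways. Of 35, 18 were higher, 8 lower and 9 not past the threshold in the arrays labelled MM231-FGD5-cas9, with a median log2 fold change of 0.19. Besides PRTN3 and RNASE2, the granule protein genes PRG2 and AZU1 rose by 1.41 ± 0.12 and 1.23 ± 0.08 (log2, SE, n = 3 each), MS4A3 by 1.22 ± 0.07, the cathepsin G gene CTSG by 0.56 ± 0.08, and CYBB, a subunit gene of the phagocyte oxidase, by 0.65 ± 0.08. The elastase gene ELANE lay below the background level in both groups, at 5.44 and 5.63. The surface protein gene CD48 fell by 2.04 ± 0.08, the receptor gene CSF3R by 0.62 ± 0.11 and the aminopeptidase gene ANPEP by 0.52 ± 0.10, and for CSF3R and ANPEP the shift of scaling to the spike-ins, 0.52, would take up most or all of this. Among lymphoid genes, 5 of 19 exceeded the background level on all arrays, among them PAX5 and NKG7, while CD3G, LCK and MS4A1 did not.

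Members of the stress and metabolism lists that were not called went both ways. In the unfolded protein response list CRELD2, MANF and PDIA4 rose by 1.02, 0.85 and 0.73 on the log2 scale and SEL1L fell by 1.09, with the same sign on 3 of its 4 probe sets, while DNAJB9 fell by 0.41 on the deposited scale but was above 0 after scaling to the spike-ins. HYOU1, DNAJC3, PDIA3 and CANX did not pass on their brightest probe sets. The sign of these was shared by 3 of 9, 1 of 3, 1 of 2 and 2 of 9 probe sets. Among immediate early and heat shock genes, 8 of 22 rose and 4 fell: the chaperonin gene HSPE1 rose by 1.41 ± 0.07 and HSP90AA1 by 1.08, while JUN and DUSP1 fell, DUSP1 by 1.24. In the glycolysis and hypoxia list the enzyme genes GPI, LDHA, PGK1 and ENO1 rose by 1.28, 0.62, 0.61 and 0.52, whereas the enzyme gene ENO2 fell by 0.73. HK1, HK2 and ALDOC did not pass, and the sign of the brightest was shared by 4 of 4, 1 of 2 and 2 of 5 probe sets. Individual members were chosen after their values were seen, and no subset was tested.

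On lists written after the values were seen, most myeloid genes were bright and most genes chosen as expressed in MDA-MB-231 cells were dim on all 6 arrays. A probe table belonging to other probe sets is argued against by the correlation across genes of 0.752 between the fold changes of the 2 brightest probe sets of 8218 genes, against at most 0.04 in 1000 shuffles. MDA-MB-231 cells as the main part of a mixture with leukocytes would keep the genes of that line bright. The 6 of 32 such genes that exceeded the background level on all arrays restate the pattern, so that count is no separate test. Of the 32 genes, 23 were also on lists fixed beforehand. Among these, CAV1 at 4.54 and 4.92 and EGFR at 5.23 and 5.32 go against such a main part, though they were picked after their values were seen. A small share of such cells stays open. On the mesenchymal list fixed beforehand 7 of 22 exceeded the background level on all arrays. The bright VIM, MSN, S100A4 and CD44 do not separate the cell types, since leukocytes express them as well. That the arrays hold RNA of myeloid cells under these labels stays open and cannot be told apart from other causes, because the 33 of 35 bright myeloid genes were chosen from what was seen and the leukocyte list fixed beforehand, 10 of 15 bright, mixes lineages: of the 5 others 4 are T or B cell markers.

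The fall of ATF4 targets held across their probe sets. Misreporting by single probe sets is argued against, since 96.6% of 59 bright probe sets of 18 targets with several probe sets were lower. Whether it follows from loss of FGD5 cannot be told apart from other causes, because FGD5 lay -1.18 log2 units from the background level in the arrays labelled MM231, where a loss would not show. A difference in medium or amino acid supply at harvest could also lower these genes and was not tested.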
